A study of Mus musculus with 2 samples.

How the data were processed

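CTCF chromatin immunoprecipitation followed by sequencing was carried out on mouse limb tissue of embryonic day 14.5. CTCF is the zinc finger protein that binds insulators and anchors chromatin loops together with cohesin. The series holds 2 libraries, numbered replicate 1 and replicate 2 in the labels, and a single group. Per the labels, both libraries came from 1 pool of pulverised limbs from several dissections of male and female embryos, so the spread between them covers library preparation and sequencing and may be technical.

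The analysis started from 5 deposited peak lists in narrowPeak format on the mm10 build. Per the notes deposited with each library, each replicate list was derived from that library's filtered alignments and 1 further file, and a pooled list was derived from the alignments of both libraries. Those notes also say that the 2 lists named conservative and optimal, which call themselves IDR thresholded (irreproducible discovery rate), were derived from both replicate lists, the pooled list and 1 further file. The aligner, the peak caller, its thresholds, the control used, and the version and threshold of the IDR step are not given in the sources used here. The deposited signal value of a peak is never negative and is on the scale of its own list, and its normalization is not given in the sources used here. The deposited −log10 q-value is capped at a value that many strong peaks share, so it was not used to rank peaks. The deposited IDR score, filled in the 2 IDR lists alone, was used only to describe peaks. The p-value column was not filled. Values per peak are the authors' own and were not recomputed. Read depth is unknown, since the lists hold no read counts. Each full list holds 300000 peaks, so its lower part is a fixed length and not a set of called sites.

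Peaks were ranked by signal within each list. The main set was the optimal list. For a comparison of equal length, the strongest 49970 peaks of each replicate list were taken, the length of the optimal list. Summits within 100 bp counted as shared. Overlap by chance was measured after shifting the summits of replicate 2 by 100 kb. Replicate signal at a peak was the signal of the nearest summit within 100 bp in the full replicate list. Signals of different lists are set side by side as descriptions, and log2 ratios between replicates were scaled by each replicate's median over the optimal peaks.

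Positions were compared with the GRCm38.p6 assembly, of which mm10 is the browser name, and with GENCODE M21 gene models. The chromosome names matched and no peak reached past a chromosome end. Peaks on the 21 main chromosomes entered all steps that used sequence or genes. A summit within 1 kb of the transcription start site (TSS) of any annotated transcript was classed as promoter, and the others as exon, intron or intergenic in that order. Repeat summits were those in soft-masked sequence. Both shares were set beside 100 random placements of the same number of summits on the same chromosomes outside assembly gaps. The motif matrix was refined in 10 rounds from the seed CCASYAGRKGGCRS on the strongest 1000 peaks of odd-numbered autosomes, and the motif share was measured on even-numbered autosomes and X. Motif shares by signal decile, genomic class and repeat used all main chromosomes, those of training included. A hit lay within 50 bp of the summit and scored at least what 5% of windows 1 kb away reached. Consecutive motif-bearing peaks were classed as convergent, tandem or divergent from their strands, beside 10000 permutations of strands within chromosomes. Convergent and divergent pairs alternate along a chromosome, so their totals are equal by construction, and only the tandem share and the distances carry information.

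For 11 gene lists fixed before the data were examined, promoter occupancy (an optimal summit within 1 kb of any TSS) was compared with all other protein-coding genes by Fisher's exact test, and the median number of optimal summits within 100 kb of the first TSS with 10000 random lists matched on local gene density (permutation test). Both tests were two-sided, with Benjamini-Hochberg adjustment over the 11 lists. Binomial intervals are exact 95% intervals over peaks or genes, which are not independent replicates, and cover counting error only. The named items followed a rule set in advance. It takes the 10 strongest optimal peaks, for each list the 3 members with the strongest promoter peak found in both replicates and the first 2 members by symbol with no promoter peak, 14 chosen gene intervals, and the 5 optimal peaks with the largest and the 5 with the smallest ratio between replicates. Not every item that the rule takes is printed. Nearest genes are the protein-coding gene with the nearest first TSS.

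The matching, motif, orientation, class, list and distance steps were tested on simulated data. Of 3000 simulated windows, 60.1% had a planted site, and all of those were found with the right strand, while 5.09% of windows without a site were called. Of 5000 simulated peaks, 69.1% were copied and 69.2% were matched. In 40 simulated gene sets, the planted list was called every time and the random lists never, in both list tests. Of 8000 simulated summits, 21.9% were classed as promoter where 22.0% were planted or due to chance. The distance ratio was called in all of 400 simulated sets with doubled convergent distances and in 5.50% of sets with no structure. The distance ratio, the genome-wide motif scan with its score deciles, the comparison with halved values, the gene families and the X-linked genes were chosen after the data were examined. Alternatives covered the overlap rule, the number of replicate peaks, the conservative list, the strongest part of the optimal list, each replicate list by itself, promoter and window sizes and motif thresholds. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The read alignments and the control libraries were not used here.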

Results

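CTCF binding was measured in limb tissue of mouse embryos at embryonic day 14.5, a stage at which the digits and the cartilage of the limb skeleton form. The 2 libraries belong to 1 group, so the comparisons are between the replicates, between the deposited lists, and between CTCF sites and the genome. Each replicate list and the pooled list held 300000 peaks, the conservative list 48829 and the optimal list 49970. Of the optimal peaks, 49959 lay on the main chromosomes. The median optimal peak spanned 276 bp and had a pooled signal of 58.4, with a range from 5.14 to 597.2. Pooled signal is given for each peak below, with the values of replicate 1 and replicate 2 where they were compared. Read depth is unknown for these lists.

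Most of the strongest CTCF sites were found in both libraries. Of the strongest 49970 peaks of replicate 1, 84.0% (41992) had a summit within 100 bp among the strongest 49970 of replicate 2, against 0.716% after a 100 kb shift. Of the optimal peaks, 88.4% were found among the strongest peaks of replicate 1, 88.2% among those of replicate 2, and 81.2% (40587) in both, while 2320 were in neither. Across the 48713 optimal peaks with a summit in both full lists, the signals of the replicates had a Spearman rho of 0.935 and a Pearson r of 0.930 on the log2 scale, across peaks that are not independent replicates. The optimal list was itself derived from both replicate lists, so its agreement between them is partly set by that selection. Within deciles of pooled signal, rho was 0.802 in the strongest, -0.197 in the fifth and -0.598 in the weakest. Each decile holds a narrow range of a signal pooled from both replicates, which lowers rho. The log2 ratio between replicates had an SD of 0.14 in the strongest decile of peaks and 0.83 in the weakest. The overlap depends on the number of peaks taken: 93.4% of the strongest 20000 peaks and 31.1% of the full lists were matched.

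The strongest site of all lay between genes at position 120102955 of chromosome 5 (peak 120102778 to 120103138), 13510 bp upstream of Rbm19, with a pooled signal of 597.2 and replicate values of 321.8 and 278.4 (300.1 ± 30.7, SD, n = 2). The second lay in an intron of Fam129b on chromosome 2 (summit 32912619), with a signal of 574.9 and replicate values of 297.2 and 281.2. The next were an intergenic site on chromosome 7 (summit 137478447), 40833 bp downstream of the Glrx3 TSS, with 573.1, and a site on chromosome 15 (summit 79243368) within Pick1 with 570.9. An intergenic site 45956 bp upstream of Lbr, the lamin B receptor gene, on chromosome 1 (summit 181889002) had 561.0. Within Iqsec1 on chromosome 6 (summit 90737589) the signal was 546.7, and 19128 bp upstream of Fnbp1l on chromosome 3 (summit 122638843) it was 546.2. The remaining 3 of the 10 strongest lay 53562 bp downstream of the Snx19 TSS on chromosome 9 (537.5), within Polr3gl on chromosome 3 (530.2) and in an intron of Col18a1, a collagen gene, on chromosome 10 (526.3). All 10 carried a CTCF motif, 5 on the forward strand and 5 on the reverse. By class, 5 were intergenic, 3 lay within 1 kb of a TSS of some transcript and 2 were intronic.

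Optimal CTCF peaks were found at promoters more often than random positions were. Promoters held 21.04% of summits (10510 peaks) against 6.37% ± 0.104 (SD over 100 placements), 3.30 times as many, and exons held 5.22% against 3.402%. Introns held 38.6% against 40.3% and intergenic sequence 35.2% against 49.9%. All 4 shares lay outside the range of the 100 placements. Intergenic sites had the highest median signal, 68.2, and promoter sites the lowest, 51.9, with quartiles of 32.1 and 161.5 for intergenic and 28.1 and 125.9 for promoter sites. A motif was present at 65.8% of promoter peaks (interval 64.9 to 66.7), 81.2% of exon peaks, 85.1% of intron peaks and 86.9% of intergenic peaks. Promoter peaks without a motif had a median GC content of 60.7% in the 201 bp window around the summit and a median signal of 32.0, and those with one had 56.2% and 74.7.

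Repeat-masked sequence held 17.4% of summits against 33.6% of random positions, and the lowest of the 100 placements had 33.1%. The placements covered all sequence outside assembly gaps, whether or not reads can be placed there uniquely. How far this widens the difference was not measured. The repeat share was 4.70% in the strongest decile of peaks and 24.9% in the weakest. Repeat summits had a median signal of 37.0 and others 67.9. The motif share was 90.9% at repeat summits and 79.5% elsewhere.

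The refined motif read TGGCCACCAGGGGGCACCA as a consensus. It was present at 18879 of 23162 peaks (81.5%, interval 81.0 to 82.0) on the chromosomes left out of training, at a score that 5% of flanking windows reached. At a score that 1% reached, the share was 61.9%. Its centre lay a median of 7 bp from the summit. Over all main chromosomes, 97.1% of peaks in the strongest decile had a motif, in the fifth 85.3% and in the weakest 55.0%. The strongest decile includes training peaks.

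**Figure D1:**
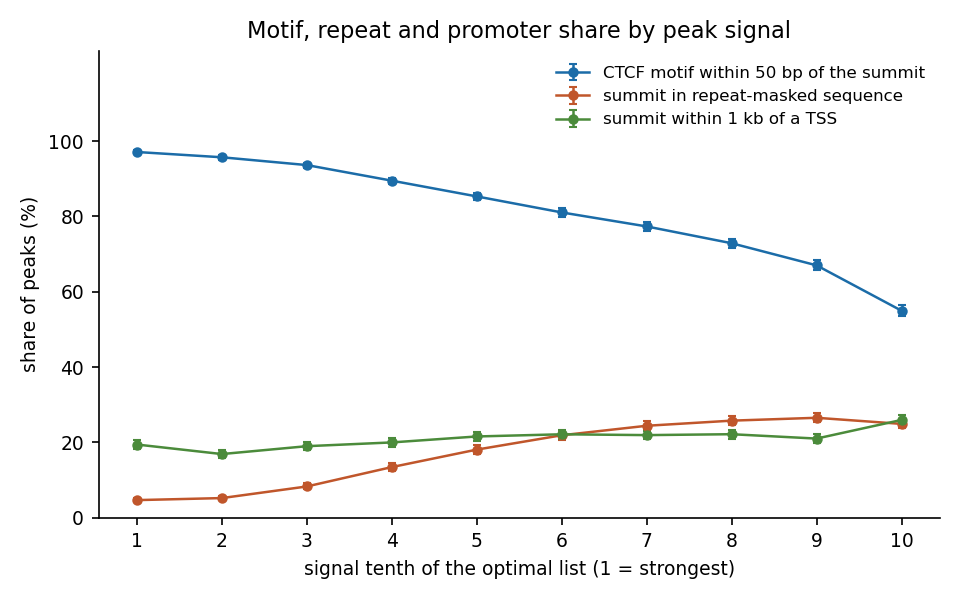
Share of optimal CTCF peaks (%, vertical axis) with a motif, in repeat-masked sequence or within 1 kb of a TSS, for each decile of the list by pooled signal (horizontal axis, 1 is the strongest), with exact 95% binomial intervals. Between the strongest and the weakest decile, the motif share goes from 97.1% to 55.0%, the repeat share from 4.70% to 24.9% and the promoter share from 19.5% to 26.0%. The repeat share is highest in decile 9 (26.6%), and the promoter share is lowest in decile 2 (16.9%).

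Neighbouring CTCF motifs that faced each other lay farther apart than those that faced away from each other. The median distance was 31.6 kb for convergent pairs, 18.4 kb for divergent pairs and 22.0 kb for tandem pairs. The ratio of convergent to divergent was 1.71, against 0.951 to 1.05 for the middle 95% of 2000 permutations of the strands (permutation p = 0.0005, two-sided, the smallest they can give). Pairs under 10 kb apart were less often convergent than divergent: at 3 to 10 kb, 19.1% were convergent and 27.6% divergent. At 100 to 300 kb, 32.4% were convergent (31.1 to 33.8) and 16.4% divergent (15.4 to 17.5), and beyond 300 kb 36.4% and 13.9%. Over all 40682 pairs, 52.2% were tandem against 50.01% ± 0.249 (SD) in the permutations (permutation p = 1e-04, two-sided, the smallest that 10000 can give). In the strongest 50% of peaks that excess was absent, with 49.7% tandem (permutation p = 0.394). The distance comparison was chosen after the data were examined.

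**Figure D2:**
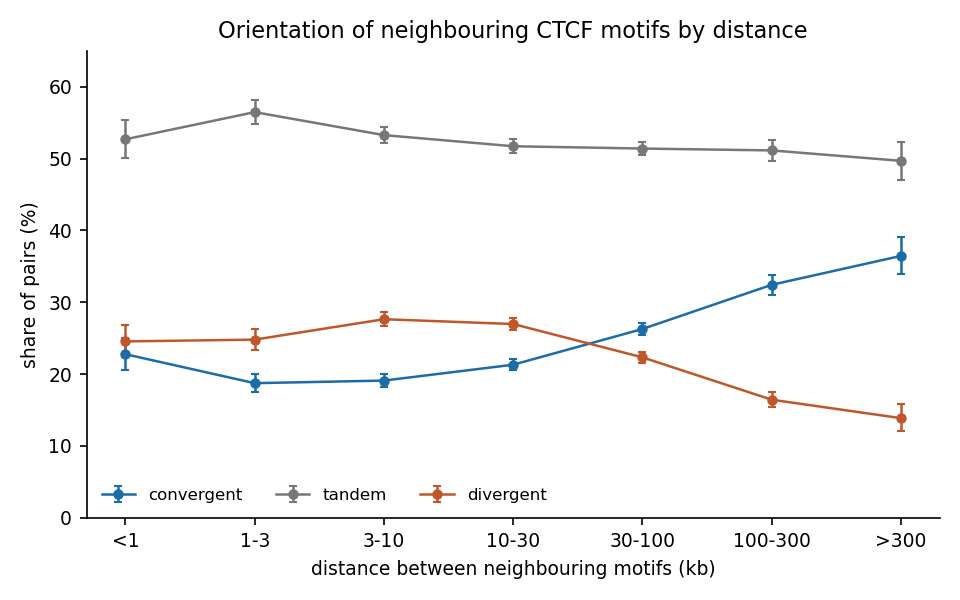
Share of convergent, tandem and divergent pairs (%, vertical axis) among neighbouring motif-bearing optimal peaks, by distance between the motifs (kb, horizontal axis), with exact 95% binomial intervals. Convergent pairs make up 19.1% at 3 to 10 kb and 36.4% beyond 300 kb, and divergent pairs 27.6% and 13.9%.

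Across 11 gene lists, clustered protocadherins had promoter CTCF more often, and liver genes less often, than other protein-coding genes, of which 33.3% to 33.4% had a peak within 1 kb of a TSS. Protocadherin genes, whose products give neurons distinct surface identities, were occupied in 32 of 57 cases (56.1%, interval 42.4 to 69.3, Fisher's exact test, p = 0.000586, adjusted p = 0.00456). The strongest were Pcdhac1 with a signal of 141.6 (74.0 and 67.2 in the replicates), Pcdhgc3 with 116.4 (53.1 and 59.2) and Pcdhgb6 with 93.0 (51.0 and 43.0). Pcdha1 and the Pcdha11 entry starting at 37005203 had no promoter peak. Another entry with the symbol Pcdha11 was left out of the list. Liver genes, a list for another tissue, were occupied in 2 of 30 cases (6.67%, interval 0.818 to 22.1, Fisher's exact test, p = 0.000829, adjusted p = 0.00456). Those 2 were Apob, an apolipoprotein gene, with 295.5 (158.4 and 138.6), and Afp, alpha-fetoprotein, with 210.8 (106.7 and 105.7). The serum protein genes Ahsg and Alb had none. Both liver peaks lay over 1 kb from the first TSS, at the start of another transcript, and with the first TSS alone 0 of 30 were occupied (Fisher's exact test, adjusted p = 0.00113). Without replicate 2 the protocadherin share was 50.9% and did not pass (Fisher's exact test, adjusted p = 0.0623), nor did it with 5 kb promoters (63.2%, adjusted p = 0.152), and the liver list did not with 5 kb promoters (33.3%, adjusted p = 0.0986, exact tests). In the strongest 50% of optimal peaks neither list passed, and the protocadherin share lay below that of other genes, 10.5% against 17.2% (exact test, adjusted p = 0.483). Protocadherin genes lie side by side in 3 clusters and are not independent, so their p is too small. Over all alternatives the adjusted p of the exact test ran from 2.30e-05 to 0.483 for protocadherins and from 0.000631 to 0.483 for liver genes.

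The other 9 lists did not pass Fisher's exact test. Where a strongest promoter peak is named, it may lie at the start of any annotated transcript, as that of Ppp1r9a does, 207675 bp from the first TSS. Among imprinted genes, 27 of 57 (47.4%) were occupied (exact test, adjusted p = 0.0932). H13 had a signal of 399.5 (204.7 and 193.7), Ppp1r9a 386.1 and Blcap 216.5, and Airn and Cdkn1c had no promoter peak. With promoters of 500 bp, the imprinted list passed with 45.6% (exact test, adjusted p = 0.00887, range over the alternatives 0.00887 to 0.483). Of 24 cohesin and CTCF machinery genes 13 (54.2%) were occupied (exact test, adjusted p = 0.106), led by Stag1 (267.0), Esco1 (236.9) and Smc3 (185.5), which encode a cohesin subunit, a cohesin acetyltransferase and a cohesin core protein. Cdca5 and Ctcfl had none. This list also passed with 500 bp promoters (54.2%, exact test, adjusted p = 0.0128, range 0.0128 to 0.483). Hox genes, which pattern the body axis and limb, were occupied in 7 of 41 cases (17.1%, interval 7.15 to 32.1, exact test, adjusted p = 0.0932). Hoxa7 had 358.7, Hoxb5 243.1 and Hoxc10 228.0, and Evx1 and Evx2 had none. With 5 kb promoters the Hox share was 68.3% and lay above that of other genes (exact test, adjusted p = 0.0986, range 0.0930 to 1.000).

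Limb patterning genes were occupied in 20 of 61 cases (32.8%, exact test, adjusted p = 1.000), and the direction changed to 39.3% without replicate 2. Among them Wnt7a, a dorsal signal of the limb bud, had 298.0 (136.7 and 159.7), and the Hedgehog effectors Gli1 and Gli2 had 287.1 (144.6 and 141.6) and 252.7 (127.8 and 125.1). Alx1 had no promoter peak. Cartilage and bone genes were occupied in 15 of 39 cases (38.5%, exact test, adjusted p = 0.612), with Col1a1, a collagen gene of bone, at 240.7, Gdf5, a joint signal, at 224.7 and Sox6, a cartilage regulator, at 193.3. Acan and Bglap had none. With 5 kb promoters that list passed, with 82.1% (exact test, adjusted p = 0.00163, range 0.00163 to 1.000). Skeletal muscle genes were occupied in 11 of 36 cases (30.6%, exact test, adjusted p = 0.946). Ckm, muscle creatine kinase, had 319.9, Tnnt1 147.9 and Myod1 106.5, and the actin genes Acta1 and Actc1 had none. Housekeeping genes reached 13 of 32 (40.6%, exact test, adjusted p = 0.612), with Rplp0 at 384.3, Rpl13a at 219.2 and Tubb5 at 185.0, and none at B2m and Chmp2a. Neuronal genes had 7 of 30 (23.3%, exact test, adjusted p = 0.523), led by Rbfox3 (319.1), Elavl4 (199.2) and Gad1 (157.1), with none at Camk2a and Dcx. Blood genes had 7 of 29 (24.1%, exact test, adjusted p = 0.523), among them Kit (135.1) and Gfi1b (115.9), with none at Alas2 and Cd34.

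**Figure D3:**
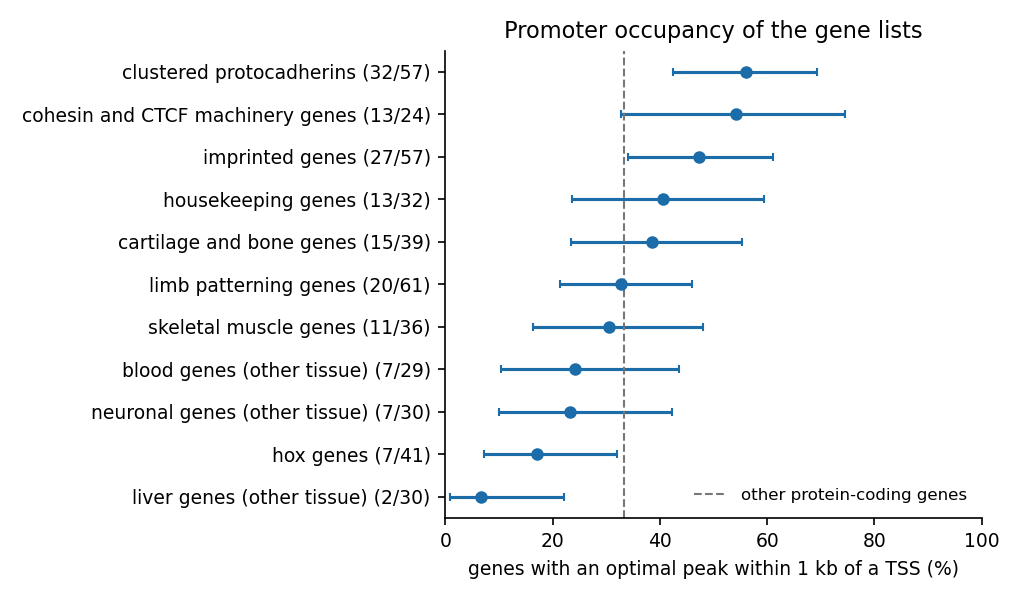
Share of genes with an optimal CTCF peak within 1 kb of a TSS (%, horizontal axis) for the 11 gene lists (vertical axis, occupied genes and list size in brackets), with exact 95% binomial intervals. The dashed line is the share of other protein-coding genes, and the lists run from 6.67% for liver genes to 56.1% for clustered protocadherins.

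In wider windows, cartilage and bone genes had more CTCF sites around them than gene lists of like local density. Their median was 9 optimal summits within 100 kb of the first TSS against 6 in random lists (middle 95% 4 to 8, permutation test, p = 0.00360, adjusted p = 0.0198). Clustered protocadherins had a lower median, 7 against 13 (10 to 15, permutation test, adjusted p = 0.00220, the smallest it can give), but a mean of 11.8 against 12.3. Their 57 genes share windows in 3 adjacent, very gene-dense clusters for which few matching genes exist, so this p is too small and the difference rests on the median alone. Imprinted genes had 7 against 5 and housekeeping genes 11 against 8 (permutation test, adjusted p = 0.0594 for both). Limb patterning genes had 6 against 4 (permutation test, adjusted p = 0.132), and skeletal muscle genes 8 against 6 (adjusted p = 0.156). The muscle list passed in the strongest 50% of peaks (5 against 3, permutation test, adjusted p = 0.0286), without replicate 1 (9 against 6, adjusted p = 0.0315) and with 250 kb windows (20.5 against 14, adjusted p = 0.0451), over a range of 0.0286 to 0.162. Hox, cohesin, liver, neuronal and blood lists had adjusted p of at least 0.617 in the permutation test. The cartilage and bone call ended with the conservative list (8 against 5, permutation test, adjusted p = 0.102), without replicate 2 (8 against 6, adjusted p = 0.137), with 50 kb windows (4 against 3, adjusted p = 0.391) and with 250 kb windows (19 against 13, adjusted p = 0.0572), over a range of 0.0187 to 0.391. Limb patterning genes passed with 50 kb windows (4 against 2, permutation test, adjusted p = 0.0154, range 0.0154 to 0.715).

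The Hox clusters, which were examined because they pattern the limb, were compared with random windows that were not matched on gene density. Against lists matched on gene density, Hox genes had a median of 10 sites against 11 (permutation test, adjusted p = 0.789). The HoxA interval (chromosome 6, 52155590 to 52318378) held 14 optimal peaks, more than most random windows of that length (98.4th percentile of 10000). HoxD (chromosome 2, 74652991 to 74765142) held 10 (97.9th percentile), HoxB (chromosome 11, 96194316 to 96368256) 11 (95.01th) and HoxC (chromosome 15, 102921103 to 103036852) 5 (85.4th). In HoxA the strongest lay 39 bp inside Hoxa7, with 358.7 (180.8 and 179.8), followed by sites in the Hoxa3 gene near position 52211734 (200.1) and 309 bp inside Hoxa10 (198.9). In HoxD the strongest lay within Hoxd4 and Hoxd3 (summit 74715932, 258.2), upstream of Hoxd12 (summit 74673160, 252.9) and upstream of Hoxd8 (summit 74702399, 247.3). Motifs at the latter pair faced opposite ways, reverse at Hoxd12 and forward at Hoxd8. HoxB was led by sites at Hoxb5 (243.1) and at 96235114 (233.7), and HoxC by sites at 102987601 (261.0) and at Hoxc10 (228.0).

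Intervals around limb genes ranged from few to many sites for their length. The Shh to Lmbr1 interval (chromosome 5, 28456815 to 29378390), which holds a distant limb enhancer of Shh in an intron of Lmbr1, had 6 peaks in 921.6 kb (25.8th percentile), led by a site in Lmbr1 at 29293407 with 250.8 (136.5 and 115.3). All 6 had a motif, 5 of them on the reverse strand. Sox9 to Kcnj2 (chromosome 11, 111066164 to 112787760) had 20 peaks (38.6th percentile), the strongest a forward pair at 111536222 and 111537850 with 203.9 and 205.2. Wnt6 to Pax3 (chromosome 1, 74771892 to 78197134), which includes Ihh and Epha4, had 82 (69.9th percentile), with an exonic site of Slc4a3 at 75559699 (461.4) and a site 1357 bp upstream of Epha4 (392.3). Pitx1 to H2afy had 12 peaks (84.6th percentile, strongest 255.5), and Grem1 to Fmn1 had 7 (53.7th percentile, strongest 190.7, within Fmn1). Tbx5 to Tbx3 (chromosome 5, 119670669 to 119885219), around genes of forelimb and digit formation, had 16 (97.5th percentile). Its strongest sites lay downstream of the Tbx3 TSS by 42399 bp (321.9, reverse motif) and 70647 bp (297.6, forward motif).

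At the imprinted Igf2 to H19 interval (chromosome 7, 142575529 to 142666816), 6 peaks were found, all in both replicates. Of these, 4 lay 1118 to 3661 bp upstream of the H19 TSS, with signals of 82.5, 122.4, 132.8 and 78.3 and reverse motifs, and the latter 3, at 2169 to 3661 bp, lay where the imprinting control region is known to be. The strongest, 152.0 (83.0 and 69.6), lay 32613 bp upstream of the H19 TSS at 142610756, between H19 and Igf2, with a forward motif. In the protocadherin clusters of chromosome 18, the alpha cluster had 8 peaks and the beta cluster 8, and their motifs (7 and 8 peaks) were on the forward strand, the strand of the genes. The gamma cluster had 21 peaks (99.9th percentile), of which 16 lay within 100 bp of a coding TSS and 5 had a motif at the threshold used. The peaks there were weak, with medians of 33.9, 26.5 and 37.6 in the 3 clusters. Only 5 of 8, 4 of 8 and 18 of 21 were found in both replicates, and without replicate 2 the alpha cluster had 5.

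**Figure D4:**
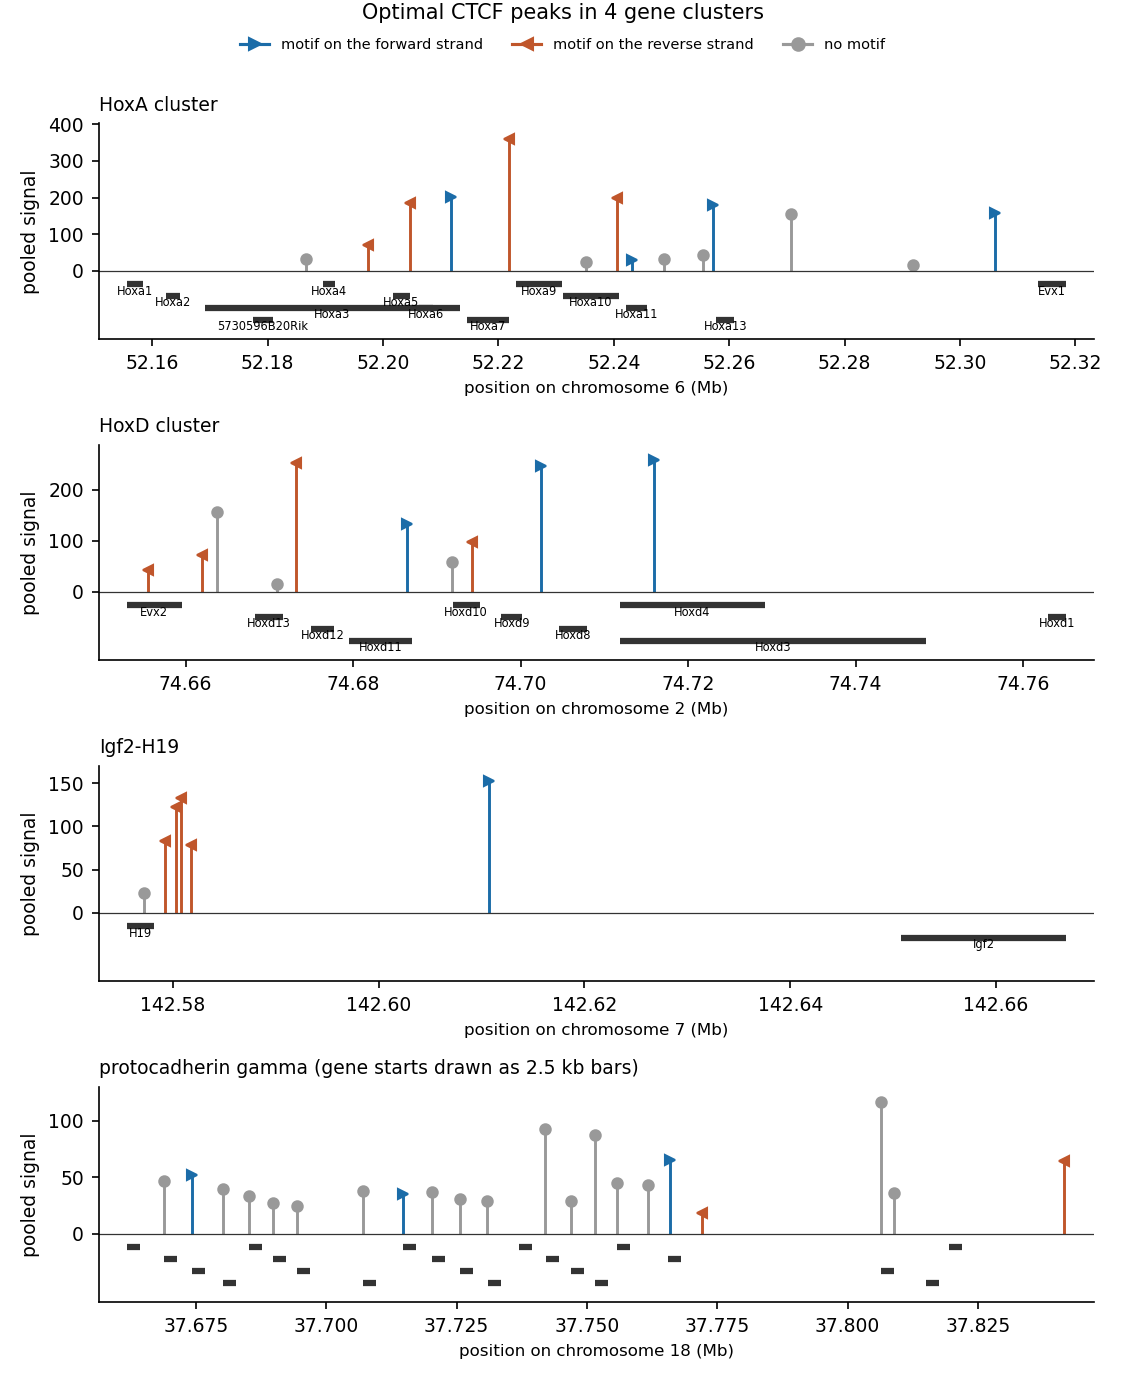
Optimal CTCF peaks (vertical lines, height is pooled signal) along 4 gene clusters by position (Mb, horizontal axis), with arrowheads for the strand of the motif, circles for peaks with no motif, and genes as bars below. The 4 peaks within 3661 bp upstream of H19 have reverse motifs and the site between H19 and Igf2 a forward one, and 16 of 21 peaks of the gamma cluster lie within 100 bp of a coding TSS.

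The 2 IDR lists differed at weak sites. They shared 43749 peaks, 87.6% of the optimal list, with a median signal of 71.9. The 6221 peaks of the optimal list alone had a median of 20.2, as did the 5080 of the conservative list alone, so neither list contains the other. Of the former, 99.9% fell in the weaker 50% of the optimal list.

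Ratios between replicates cover only optimal peaks with a summit in both full replicate lists. Of these, the peaks with the largest ratios all had a pooled signal below the median of the optimal list, from 22.3 to 54.2. After scaling to the medians of 31.2 for replicate 1 and 29.5 for replicate 2, the largest log2 ratios of replicate 1 over replicate 2 were 3.15 at the Tfip11 promoter (26.8 and 2.86), 2.96 near Dbx1, 2.93 near Tmem86a, 2.79 near Cavin1 and 2.69 in Myo18b. The smallest were -3.15 upstream of Plekhg6 (5.70 and 47.8), -2.89 at the Tars promoter (3.51 and 24.6), -2.87 near N4bp1, -2.71 in Dock10 and -2.71 in Hdac9. With 1 value per replicate, these differences have no test. The lowest listed signal was 3.05 in replicate 1 and 2.86 in replicate 2, and the lower value of several pairs lay near it.

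CTCF sites on the X chromosome were fewer and weaker than on autosomes. X held 1153 optimal peaks, 7.05 per Mb of sequence, against 20.4 per Mb on autosomes, where the range was from 15.6 on chromosome 3 to 31.0 on chromosome 11. Of the strongest 10000 peaks, 58 were on X. The median log2 signal of X peaks minus that of autosomal peaks was -0.16 in the pooled list, -0.16 in replicate 1 and -0.21 in replicate 2. At the 90th percentile the difference was -0.82, -0.82 and -0.84. In the strongest 50% of peaks the median difference was -0.61. The strongest X peak, at 94865737 near Zxdb, had 440.8 (245.2 and 199.3). The Y chromosome had no optimal peak.

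**Figure D5:**
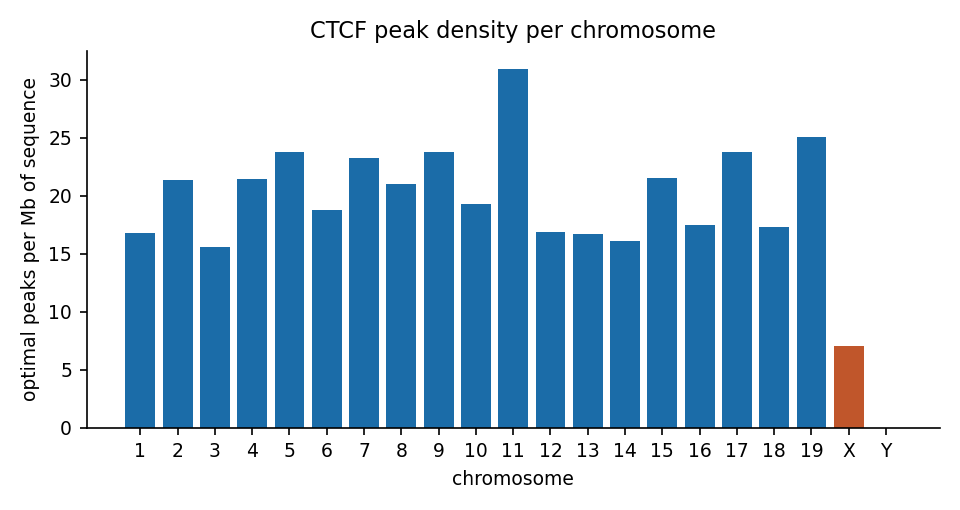
Optimal CTCF peaks per Mb of assembled sequence (vertical axis) on each chromosome (horizontal axis), autosomes in blue and sex chromosomes in orange. X has 7.05 peaks per Mb and Y none, and the autosomes run from 15.6 to 31.0.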

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

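Of the tests below, those of repeat copies of motifs and of IDR scores taken from a stronger replicate peak were set before the result they measure was seen, and all others, including those of the X and Y chromosomes, of the strongest peaks and of the motif share, were chosen only after.

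Optimal peaks on scaffolds and strong pooled peaks outside the optimal list were looked at again. The former entered the comparisons of replicates and lists, but no step that used sequence or genes. The latter were used in the search for stronger summits and in the tests of motif instances on X and Y. On scaffolds, 11 optimal peaks lay on 7 sequences, with a median signal of 37.3, a highest of 439.4, and 6 of them among the strongest peaks of both replicates. In the pooled list, 12 of the 24993 peaks stronger than the optimal median of 58.4 had no optimal summit within 100 bp. Their highest signal was 220.9, 8 were among the strongest peaks of both replicates, 11 had a motif, and 4 lay within 300 bp of an optimal summit.

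X had fewer and weaker peaks than autosomes. Its density of non-repeat motif instances was 0.530 times the autosomal one. The density of all optimal peaks, which include repeat summits and peaks without such a motif, was 0.346 times the autosomal one. Of the non-repeat instances, 20.5% on X and 27.7% on autosomes had an optimal peak, so fewer motifs do not account for all of it. Nor do weaker motifs at the highest scores, since in the top score decile the median pooled signal was 76.9 on X and 166.2 on autosomes. These medians cover the instances with a listed peak, 226 of 286 on X and 7792 of 8511 on autosomes. The log2 difference among them was -1.11 (bootstrap interval -1.33 to -0.90 over instances). Scores were not matched within that decile, but the autosomal median in the decile of scores just below was 92.7, still above that of X. If signal scales with copies per cell, an equal mix of male and female embryos with every X copy bound alike predicts -0.42, above the upper bound of -0.90. The halving and the equal-mix share for Y below rest on the same assumption. It cannot be checked here, because the normalization of the signal and the control are not given. Binding on 1 X copy per cell predicts a halving, which is consistent with the lower bound of -1.33 and with the intervals of all 10 score deciles once values under the lowest listed signal are dropped, though only 2 of those intervals exclude no difference. Of the top-decile X instances, 79.0% had a listed peak (exact interval 73.8 to 83.6). After halving the autosomal values, 89.9% would. X lay below the halved share in 3 deciles, while in the other 7 the interval held it. Whether the halving accounts for all missing peaks stays open, since these instances include sequence found more than once, where a missing peak may not mean missing binding. Of 1535 higher-scoring X instances 44.95% had a listed peak, and of the 1349 whose sequence is found once 50.7% did. The halved share was not calculated for sequence found once. The same limit holds for the 20.5% and 27.7% above. A pool of nearly all male embryos predicts the same halving as binding on 1 X copy per cell and cannot be told apart from it. None of 91 Y instances had a listed peak, which was known before the test was narrowed to the 13 whose sequence is found once. Their share was 0% (exact upper bound 24.7%), against 50.7% on X and 56.8% on X at like scores. An equal mix with every X copy bound alike, which the X signal argues against, predicts 46.9%, also above that bound. The share for an equal mix with 1 bound X copy per cell was not calculated. These Y sites therefore do not measure the share of males, for a reason that was not tested.

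Convergent neighbouring motifs lay farther apart than divergent ones. Repeat copies of motifs as the cause are argued against by summits outside repeats, where the ratio of convergent to divergent median distance was 1.83 (permutation p = 0.0005, the smallest that 2000 can give). Chance motifs at weak peaks are argued against by the strongest 50% of peaks, where the ratio was 2.45 (permutation p = 0.0005). No biological explanation was tested, since the design has a single group.

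Some weak peaks of the optimal list had high IDR scores. A stronger pooled summit lay within 300 bp of 374 optimal peaks, which had a median signal of 8.57 and a median score of 872.5, and these made up 223 of the 259 optimal peaks with a signal below 10. A separate reproducible site beside the stronger one stays open: in their middle signal range 22.0% had a motif (exact interval 16.3 to 28.7), against 36.7% of other optimal peaks weighted to the same signals (bootstrap interval 22.9 to 51.4), and only 28 of those others had a signal below 10. A score taken from the stronger overlapping replicate peak stays open too, since 47.1% of them overlapped a top-ranked replicate peak without a top-ranked summit of their own, short of the 50% set before. No biological explanation was tested.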

How the results depend on the processing

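The class, repeat and motif shares of the optimal list without the peaks beside a stronger summit were chosen after seeing the data. So were the list tests with the first TSS or coding members alone, and the distance ratio. The tandem excess kept its direction and its side of 0.05 in the 7 alternatives run (51.0% to 52.4%) except the strongest 50% of peaks (49.7%), and the ratio of convergent to divergent distance stayed above 1 in all 7 alternatives (1.68 to 2.45). The overlap of the strongest peaks (84.0%) was 84.9% with any overlap of intervals, 81.6% with summits within 50 bp, 80.2% with reciprocal overlap, 93.4% for the strongest 20000 and 31.1% for all peaks, and the share of optimal peaks found in both replicates (81.2%) was 81.9%, 79.8%, 71.9%, 37.4% and 97.5%, the last pair set by the number of peaks taken. The rank correlation (0.935) was 0.957 with the conservative list, 0.949 in the strongest 50% and 0.941 within 50 bp. The promoter share (21.04%) was 19.4% in the strongest 50%, 20.9% without peaks beside a stronger summit, 15.2% with 500 bp promoters, which are narrower by construction, and 21.2% to 21.3% with either replicate left out. The repeat share (17.4%) was 9.97% in the strongest 50% and 16.8% to 17.2% with either replicate left out. The motif share (81.5%) was 82.0% with the conservative list, 92.5% in the strongest 50%, 81.9% without peaks beside a stronger summit, 61.9% at the 1% score, 75.4% within 100 bp, where the threshold rises with the window, and 80.1% to 80.6% with either replicate left out. The X difference was -0.61 in the strongest 50%. For other moves the cause was not tested.

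The number of lists past the promoter test (2) was 0 in the strongest 50%, 4 with 500 bp and 1 with 5 kb promoters, and 1 to 2 with either replicate left out. The number past the density test (2) was 1 with the conservative list, 3 in the strongest 50% and 1 to 3 with either replicate left out. Promoter shares changed side of the other genes for Hox (68.3%), limb patterning (68.9%), muscle (61.1%) and neuronal genes (70.0%) with 5 kb promoters, for protocadherins (10.5%), muscle (22.2%) and blood genes (17.2%) in the strongest 50%, for muscle genes with the conservative list (33.3%), for cartilage and bone genes with the first TSS (25.6%), and for limb patterning genes without replicate 2 (39.3%) but not without replicate 1 (32.8%). Median density changed side for Hox genes in the strongest 50% (7) and with 50 kb windows (7), and for liver genes in the strongest 50% (4.50). None of these reversed values passed the test, and the cause was not tested. Unknown read depth leaves open how far the lower ranks reflect sampling.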

Other observations

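Gene families that the lists do not cover were examined after seeing the data, by the same promoter test, with adjustment over 8 families. Olfactory receptor genes, expressed in the nose, had a promoter CTCF peak in 8 of 1134 cases (0.705%, interval 0.305 to 1.39), against 35.2% of other protein-coding genes (Fisher's exact test, adjusted p = 7.04e-189). Vomeronasal receptor genes, which serve pheromone sensing, had 0 of 328 (upper bound 1.118%, exact test, adjusted p = 2.87e-58), and keratins with keratin-associated proteins had 2 of 110 (1.82%, exact test, adjusted p = 2.32e-16). Cytochrome P450 genes (18 of 100, exact test, adjusted p = 0.00142) and replication-dependent histone genes (13 of 67, adjusted p = 0.0182) were also below other genes. Ribosomal protein genes (49 of 96, 51.0%, exact test, adjusted p = 0.000899) and solute carriers (145 of 371, 39.1%, adjusted p = 0.0259) were above, and zinc finger protein genes did not pass (145 of 394, 36.8%, adjusted p = 0.161). Where family members lie in clusters, the genes are not independent and the p-values are too small. How far each family is clustered was not measured. The test counted a peak at any TSS, which gives genes with more transcripts more chances. Of protein-coding genes outside the Hox list, 33.4% had a peak at any TSS and 26.1% at the first TSS. The families were not tested with the first TSS alone, so the smaller differences, such as those of cytochrome P450 and histone genes, may depend on it. Whether promoter sequence is found once in the assembly was not measured either, so a missing peak may not mean missing binding.

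On X, noncoding genes picked after the data were seen had uneven numbers of sites. Firre, whose RNA and repeats are known to bind CTCF, held 24 optimal peaks in 79.6 kb (chromosome X, 50555744 to 50635321), 20 of them in both replicates, and 0.0200% of 10000 random X windows of that length had as many. Their signals reached 106.6 (54.9 and 49.9 in the replicates), and the second strongest X peak (327.9; 170.1 and 158.5) lay 22.7 kb beyond its start. Tsix, the antisense partner of Xist, held 6 peaks in 53.4 kb (0.190% of windows), 2 of them within Xist, led by 129.8 at 103477693. The noncoding gene 4933407K13Rik had 4 peaks in 57.8 kb (1.22% of windows), Ftx had 1 and Jpx 0. Of the other X genes examined at the same time, which are protein-coding, Mid1 had 4 peaks in 320.5 kb (25.7% of windows), Kdm6a had 1, and Kdm5c and Ddx3x had 0.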
